A study of Mus musculus with 79 samples.

How the data were processed

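RNA of fetal brain and placenta from mice at gestational day 17 was sequenced after the dams had been given chlorpyrifos (CPF), deltamethrin (DM) or corn oil. Per the labels' protocols, RNA was purified with RNeasy columns, and libraries were made from 1 µg of RNA after ribosomal RNA had been removed by RNase H digestion. The authors deposited 1 table per library with raw read counts per gene, whole numbers that are not normalized. Per the submitters' processing notes, reads were checked with FastQC and MultiQC, aligned with STAR 2.7.5b and counted with featureCounts, with the genome build GRCm38.p6. The strand setting of the counting and the annotation release are not given in the sources used here, so a gene and its antisense or overlapping neighbour cannot be kept apart, and members of gene families with near-identical copies are uncertain. Of the 54838 gene identifiers, 54809 matched the GENCODE vM21 annotation of GRCm38 when version numbers were ignored. The 29 others took at most 0.0068% of the counts of a library, and 0 entries named no gene. Ribosomal depletion keeps RNA without poly(A) tails, such as histone mRNA, in the libraries.

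Groups were taken from the sample titles and treatment labels. Title codes came in 2 forms, with and without a hyphen between the letters and the number, and codes of 1 form may have been collected or prepared together. It was therefore fixed before the data were examined that each pesticide would be compared with the controls of its own form, in 4 groups per tissue, and that the 2 control sets would be compared with each other. The labels give neither litter nor dam, nor fetal sex. Libraries of a group were compared pair by pair with a chi-square test over genes, and no pair came close to sampling noise (lowest chi-square per degree of freedom 6.42), so that each library counted as 1 replicate. Total counts were 40779368 to 42320394 per brain library and 42131589 to 43795738 per placenta library. At this depth counting error is small for all but the lowest genes beside the spread between libraries, for which edgeR's common biological coefficient of variation was 0.366 in brain and 0.295 in placenta.

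Counts were analysed per tissue in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, which left 20429 genes in brain and 19301 in placenta, TMM normalization, robust dispersion estimates, and the quasi-likelihood F test of each contrast in a model of 4 group means. P-values are 2-sided and adjusted by Benjamini and Hochberg, with calls at an adjusted p under 0.05. Tested contrasts were CPF minus plain-coded controls, DM minus hyphen-coded controls, plain-coded minus hyphen-coded controls, and the difference of the first 2. A fit of all 79 libraries in 8 groups (22910 genes) tested whether the change in brain differed from that in placenta. Levels in the text are CPM on TMM-scaled library sizes, mean ± SD over libraries, and log2 CPM values have a prior count of 2. Standard errors of log2 fold changes were derived from the F statistics.

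The genes named were set by a rule fixed before the data were examined. It took, per pesticide comparison, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM in a group, without predicted genes, clone names, pseudogenes, Xist and Y-linked genes. It added from each fixed list up to 4 called members with the smallest p, of which the text gives part, and in every case Ache, Bche, Pon1, Scn1a, Scn2a, Scn3a, Scn8a and Cyp1a1 where tested. Where fewer than 10 genes passed, the 10 with the smallest p were named as not passing. For the 2 control sets, for CPF against DM and for the tissues, examples were chosen from these same names, and others are marked as chosen after their values were seen.

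In the same way 63 gene lists of pathways and cell types were fixed, of which 62 had at least 5 tested genes in a tissue. Each list was tested against the other genes with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01, and again with a correlation estimated per list. Members past the threshold were counted over all genes tested and adjusted over the list alone. Weighted co-expression modules were built in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3) from the 5000 most variable genes of each tissue, with a signed network at power 12, modules of at least 30 genes, and merging of modules whose eigengenes correlated above 0.8. The tree was divided at the height, between 0.5 and 0.99, that gave the most modules. Eigengenes were compared by exact permutation tests, or with 100000 resamples where both groups held 10 or more libraries, adjusted over the modules of a tissue.

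Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom with sample quality weights, RLE size factors, no filter on low counts, a filter at 1 CPM, a Y-linked score of 4 genes as a covariate, 2 surrogate variables from sva 3.50.0, pooled controls, the controls of the other code form, only the 2 groups compared, a replicate block, an estimated correlation for the lists, and 3000 genes or power 6 for the modules. Alternatives chosen after seeing the data were an embryonic globin score (mean log2 CPM of Hbb-y, Hbb-bh1 and Hba-x), skeletal muscle, hindbrain and spinal cord, cartilage and bone, and meninges scores in brain and a yolk sac score in placenta as covariates (mean log2 CPM of the fixed list), leaving out each library in turn, leaving out every brain library with Hoxb4 over 10 CPM, leaving out 1 control brain or 2 placentas with unusual sex-linked RNA (Xist between 150 and 300 CPM in placenta), and, for the tissue difference, limma-voom without weights, alone and with a block shared by both tissues. The closing section gives their effect. The globin score was compared between groups by permutation tests of the difference of means, and with the module eigengenes, built without erythroid genes, by correlation of deviations from the group means, permuting libraries within groups. With total counts alone as scaling, the median log2 fold change of all genes moved from 0.02 to −0.12 for DM in placenta, from −0.02 to −0.14 between the control sets of placenta, and from 0.00 to 0.17 for CPF against DM there, so that changes in the text are relative to the TMM scaling.

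The steps were tested on simulated counts drawn from the means and depths of the real libraries with 200 changed genes. Changed genes were picked only among those with higher mean counts, and genes were drawn independently, without the variation that genes of the real libraries share. The shares below are thus not those of all genes tested. With edgeR, 8 unchanged genes were called for CPF in brain, 3 for DM in brain, 6 for CPF in placenta and 6 for DM in placenta. At 1.5-, 2- and 4-fold, edgeR recovered 50.7%, 79.1% and 98.5% of the changed genes for CPF in brain (20429 genes), 64.2%, 82.1% and 97% for DM in brain, 79.1%, 95.5% and 100% for CPF in placenta (19301 genes) and 85.1%, 82.1% and 100% for DM in placenta. The module step put 88.5% of 400 simulated co-varying genes among 1000 into their own modules with the brain libraries, and 86.8% with the placenta libraries. Figures were drawn with matplotlib 3.10.9.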

Results

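Pregnant C57BL/6J mice, an inbred laboratory strain, were dosed by gavage with chlorpyrifos (CPF), an organophosphate insecticide that inhibits acetylcholinesterase, with deltamethrin (DM), a pyrethroid insecticide that acts on voltage-gated sodium channels, or with corn oil alone. Dosing was every 3 days and began 2 weeks before breeding. RNA of fetal brain and of placenta was sequenced at gestational day 17 in 79 libraries, 32 of brain and 47 of placenta. The codes in the sample titles came in 2 forms. All DM codes and part of the control codes have a hyphen after the letters (hyphen-coded), while all CPF codes and the other control codes have none (plain-coded). What the forms stand for is not given in the sources used here, so each pesticide was compared with the controls of its own code form. The brain groups held 6 CPF, 8 plain-coded control, 8 DM and 10 hyphen-coded control libraries, and the placenta groups held 16, 9, 12 and 10 in the same order. Total counts per library ran from 40779368 to 42320394 in brain and from 42131589 to 43795738 in placenta, so that depth differed little between libraries. Genes detected ran from 24983 to 27231. In placenta the control sets did not overlap in genes detected (25625 to 25975 hyphen-coded, 25100 to 25354 plain-coded). The labels do not say which fetuses shared a litter, and the p-values measure the spread between these samples.

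The controls of the 2 code forms differed in their embryonic globin RNA. Hbb-y, Hbb-bh1 and Hba-x encode the globins of the first, yolk sac derived red cells, which are replaced by other red cells as gestation goes on. Their mean log2 CPM (CPM, counts scaled to library size) was 7.56 ± 0.440 (SD, n = 10) in hyphen-coded control brains, 4.61 ± 2.21 (n = 8) in plain-coded control brains, 6.92 ± 0.661 (n = 6) with CPF and 2.13 ± 2.75 (n = 8) with DM. In placenta the values were 8.12 ± 0.332 (n = 10), 4.91 ± 2.48 (n = 9), 5.93 ± 1.31 (n = 16) and 4.37 ± 2.95 (n = 12) in the same order. This score was chosen after the data were examined. By 2-sided exact permutation tests, adjusted over 6 comparisons, it differed in brain for CPF (adjusted p = 0.0416), DM (adjusted p = 0.000137) and the control sets (adjusted p = 0.00199). In placenta it differed for DM (permutation test) and the control sets (exact permutation test), each with adjusted p = 0.00174, but not for CPF (adjusted p = 0.192).

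**Figure D1:**
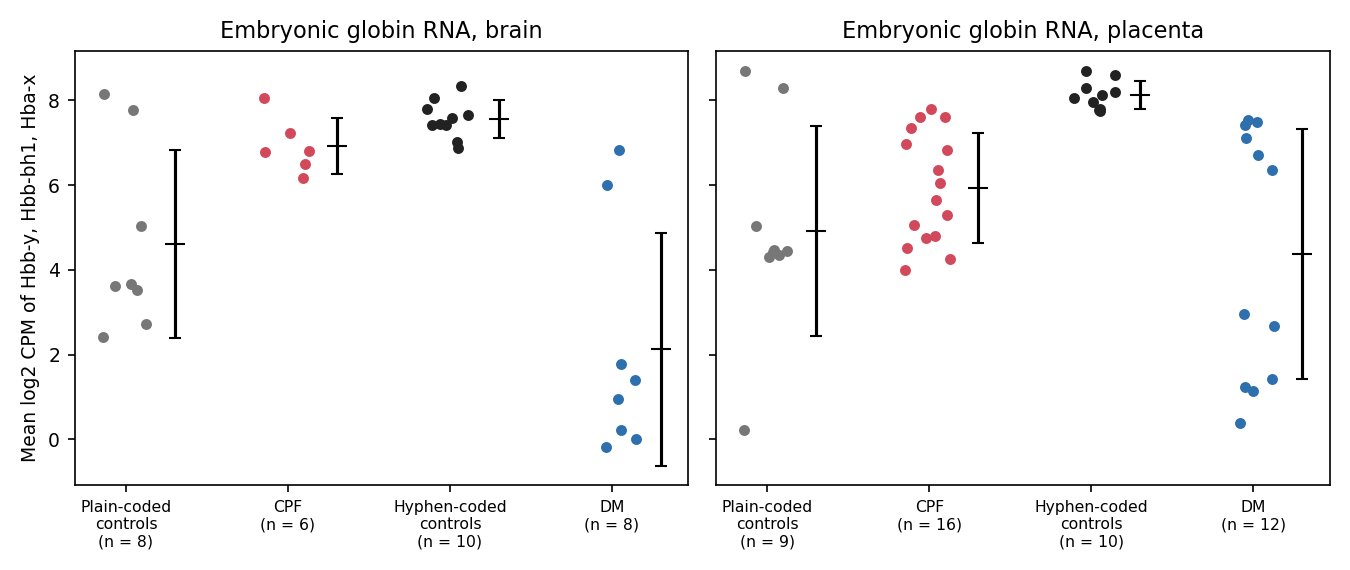
Embryonic globin score (mean log2 CPM of Hbb-y, Hbb-bh1 and Hba-x) of each library by group, brain on the left and placenta on the right, with points for libraries and bars for the mean ± SD. Hyphen-coded control brains lay between 6.87 and 8.34, while DM brains ran from −0.19 to 6.84 and plain-coded control brains from 2.41 to 8.15.

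The first comparison asked which genes of the fetal brain differed after CPF. Vegfa, which encodes a secreted growth factor for blood vessels, rose 1.33-fold. Its level was 96.8 ± 5.24 CPM (SD, n = 6) with CPF and 72.6 ± 6.21 CPM (n = 8) in plain-coded controls, a log2 fold change of 0.41 (SE 0.06, adjusted p = 0.00495, edgeR). Each of the 6 CPF libraries lay above the highest of the 8 controls, which was at 6.35 log2 CPM. Vegfa (ENSMUSG00000023951) is a protein-coding gene on chromosome 17, from 46016993 to 46032369 in GRCm38. With edgeR it was the only gene past an adjusted p of 0.05 among 20429 tested, while 1398 genes had an unadjusted p under 0.05 and DESeq2 called 4. The call ended at about the same fold change with only the 2 groups in the fit (log2 fold change 0.41, adjusted p = 0.236), with a replicate block (0.43, adjusted p = 0.815) and without the brain libraries with Hoxb4 over 10 CPM (0.42, adjusted p = 0.586). It also ended with both control sets pooled (0.31, adjusted p = 0.1001), and the adjusted p ranged from 7.93e-07 to 0.815 over all alternatives. CPF brains set against the hyphen-coded controls instead gave 2601 calls.

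Of the genes with the next smallest p, none passed in brain after CPF. Apold1, an endothelial gene, stood at 8.49 ± 1.22 CPM against 5.48 ± 0.994 (log2 fold change 0.63, adjusted p = 0.0654). Dio3, which inactivates thyroid hormone, stood at 11.3 ± 1.71 against 6.20 ± 1.23 CPM, and Depp1 at 10.1 ± 2.21 against 3.89 ± 2.05 CPM (adjusted p = 0.621 for both). The same adjusted p was found for Ciart (log2 fold change 0.60), Hdac9 (−0.30), Dnah1 (0.32) and Ctnnd1 (0.34). The lens crystallin genes Cryba1 (log2 fold change 7.25, SE 1.86) and Crybb3 (4.04, SE 1.05) were high in 1 library, CPF replicate 9, and Cryba1 averaged 15.3 ± 37.2 CPM. Ache, which encodes the enzyme that CPF inhibits, was at 28.5 ± 12.7 CPM with CPF and 30.1 ± 14.8 CPM in controls (log2 fold change −0.08, SE 0.39, adjusted p = 0.951). Bche, a related esterase, had a log2 fold change of 0.14 (adjusted p = 0.884). The sodium channel genes Scn1a (−0.58, adjusted p = 0.621), Scn2a (−0.51, adjusted p = 0.621), Scn3a (−0.25, adjusted p = 0.690) and Scn8a (−0.29, adjusted p = 0.621) did not pass either. Pon1 and Cyp1a1 had too few counts in brain to be tested.

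Among the fixed gene lists in CPF brains, 8 stood higher and 5 lower than other genes with camera at a preset correlation, and 0 of these 13 held with an estimated correlation. The 43 cytosolic ribosomal protein genes had a median log2 fold change of 0.22 (adjusted p = 5.42e-14) and the 30 extracellular matrix genes one of 0.71 (adjusted p = 1.02e-05). It was, for the 30 cell cycle genes, 0.24 (adjusted p = 7.91e-05) and for the 29 imprinted genes 0.47 (adjusted p = 0.000513). The 18 angiogenic factors and receptors, Vegfa among them, had a median of 0.21 (adjusted p = 5.35e-07), the interferon response genes 0.45 (adjusted p = 0.0236) and the endothelial genes 0.19 (adjusted p = 0.0342). Lower medians were found for 21 synaptic vesicle genes (−0.40, adjusted p = 7.84e-07), 28 glutamate receptor genes (−0.38, adjusted p = 6.22e-06), 19 GABA genes (−0.44, adjusted p = 8.77e-06). They were also found for the 17 genes of the sodium channel list (−0.30, adjusted p = 0.000238) and 14 markers of excitatory cortical neurons (−0.35, adjusted p = 0.00579). For all of these, adjusted p = 0.765 with an estimated correlation. The 26 hypoxia and glycolysis genes had a median of 0.16 (adjusted p = 2.66e-05, adjusted p = 0.141 with an estimated correlation). In none of these lists did a gene other than Vegfa pass over all genes tested, and adjusted over the list alone 5 hypoxia and glycolysis genes passed. When CPF was set against the hyphen-coded controls, all 5 of the lower lists turned to the higher side and the cell cycle list to the lower side. Markers of hindbrain and spinal cord had a median of 1.18 in CPF brains, with 0 of 15 past the threshold with edgeR (adjusted p = 0.752 with camera). The embryonic globin score of CPF brains lay above that of their own controls.

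The second comparison asked the same of DM in brain. Genes of mature synapses rose and genes of dividing cells fell. Grin1, the obligatory subunit of NMDA-type glutamate receptors, was at 65.9 ± 28.9 CPM with DM (SD, n = 8) and 17.7 ± 4.84 CPM in hyphen-coded controls (n = 10; log2 fold change 1.89, SE 0.27, adjusted p = 7.80e-06). Mki67, a marker of cycling cells, was at 131 ± 76.7 against 298 ± 92.7 CPM (−1.19, SE 0.25, adjusted p = 0.000507). In all, 9034 of 20429 genes passed, 4625 higher and 4409 lower, with a median size of 0.60 on the log2 scale, and 2283 of them differed by over 2-fold. Against the plain-coded controls, however, DM brains gave 0 calls with edgeR (2884 genes at an unadjusted p under 0.05), and Grin1 stood at 44.1 CPM in those controls. With the embryonic globin score as a covariate, 0 genes passed with edgeR (550 at an unadjusted p under 0.05). The scores of DM and hyphen-coded control brains did not overlap, so that fit rests on a straight line extended between them.

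Markers of hindbrain and spinal cord also lay apart between DM brains and their controls without passing. The list of excitatory cortical neuron markers, given below, did pass with camera at the preset correlation. The 15 hindbrain and spinal cord genes had a median log2 fold change of −1.30 (0 past the threshold with edgeR, adjusted p = 0.587 with camera). Hoxb4, a patterning gene of hindbrain and spinal cord, was at 3.8 ± 5.34 CPM with DM and 11.99 ± 16.5 CPM in hyphen-coded controls (adjusted p = 0.308), and Tbr1, a gene of cortical neurons, at 162 ± 107 and 57.8 ± 81.4 CPM (adjusted p = 0.128). Both were named after their values were seen. In hyphen-coded controls 1 to 4, Hoxb4 ran from 14.7 to 43.7 and Tbr1 from 0.531 to 10.5 CPM of total counts. Without the 4 hyphen-coded controls and 1 DM brain with Hoxb4 over 10 CPM, and the libraries of the other groups above that level, 7025 genes passed for DM, 4135 higher and 2890 lower.

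**Figure D2:**
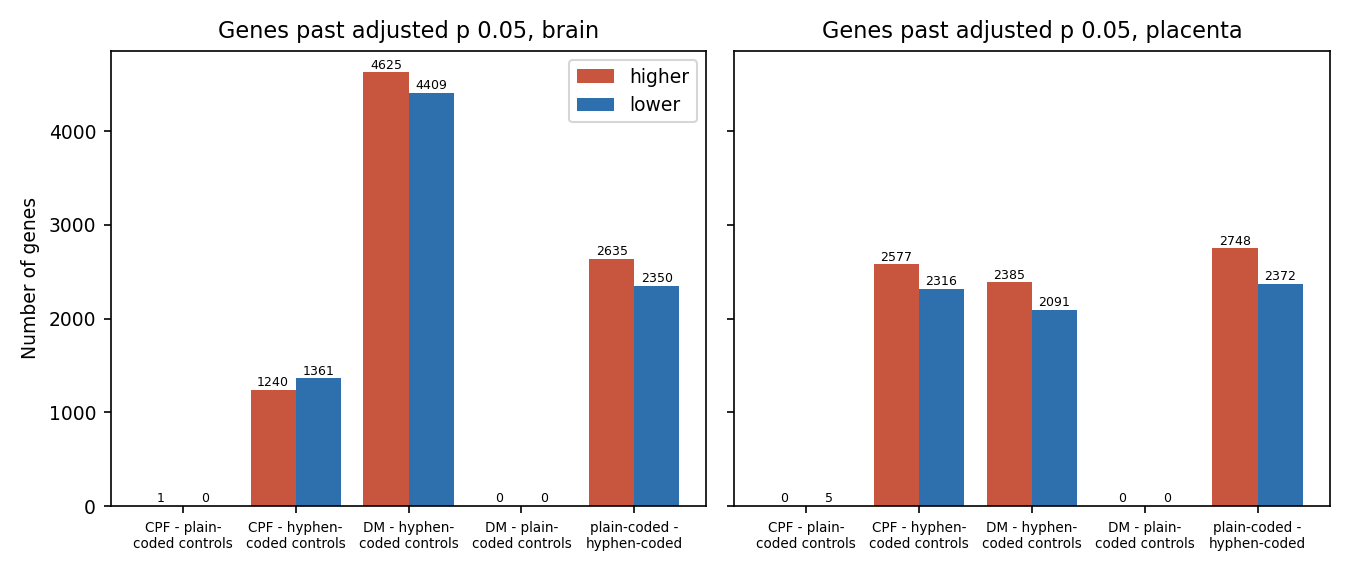
Number of genes past an adjusted p of 0.05 (edgeR), higher and lower, for each comparison in brain and placenta. DM against hyphen-coded controls gave 9034 genes in brain and 4476 in placenta, CPF against plain-coded controls gave 1 and 5, and plain-coded against hyphen-coded controls gave 4985 and 5120.

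Of the fixed lists, 12 stood higher and 3 lower in DM brains with camera, none with an estimated correlation (adjusted p = 0.952 for extracellular matrix, 0.893 for cholesterol synthesis and 0.8785 for the others). Among 21 synaptic vesicle genes 20 rose (20 adjusted over the list alone; median log2 fold change 1.09, adjusted p = 3.29e-10). They included Stx1a (1.14, SE 0.16) and Vamp2, which helps vesicles fuse with the membrane (437 ± 108 against 217 ± 32.0 CPM; 1.01, SE 0.14). Of 28 glutamate receptor and postsynaptic genes 26 rose (28 adjusted over the list alone; median 0.95, adjusted p = 2.88e-11). Camk2b was at 242 ± 83.0 against 62.2 ± 16.5 CPM (1.96, SE 0.26) and Dlg2 had a log2 fold change of 1.66 (SE 0.24). Of 19 GABA genes 16 rose and 1 fell (16 and 1 adjusted over the list alone; median 1.12, adjusted p = 4.04e-07). Gabra5 was at 43.3 ± 20.4 against 7.30 ± 2.28 CPM (2.57, SE 0.33), followed by Gabrg3 (2.40, SE 0.32). Of 17 genes of the sodium channel list 9 rose (9 adjusted over the list alone; median 0.62, adjusted p = 0.00711). Scn3b was at 0.95 (SE 0.17), and Fgf12, which is on the list but encodes no channel, at 1.23 (SE 0.20). Of 14 markers of excitatory cortical neurons 7 rose (7 adjusted over the list alone; median 0.94, adjusted p = 0.00727). These included Satb2 at 66.2 ± 64.8 against 14.9 ± 8.52 CPM (2.15, SE 0.53) and Neurod2 (1.90, SE 0.49). Of 58 nuclear genes of oxidative phosphorylation 46 rose (47 adjusted over the list alone; median 0.25, adjusted p = 1.07e-12), such as Ndufa8 (0.49, SE 0.07) and Uqcrq (0.48, SE 0.08). Of 13 mitochondrial mRNAs 10 rose (11 adjusted over the list alone; median 0.38, adjusted p = 0.000361). Against the plain-coded controls the oxidative phosphorylation list turned to the lower side. With both control sets pooled, the calls of Uqcrq (0.22, adjusted p = 0.124) and Neurod2 (1.02, adjusted p = 0.106) ended.

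In the other direction, 29 of 30 cell cycle genes fell in DM brains (30 adjusted over the list alone; median −0.80, adjusted p = 2.88e-11). Mcm4, part of the replication helicase, was at 57.1 ± 23.8 against 104 ± 23.3 CPM (−0.87, SE 0.19) and Ccne2 at −0.62 (SE 0.13). Of 30 extracellular matrix genes 16 fell (16 adjusted over the list alone; median −1.01, adjusted p = 2.98e-06). These included Fn1 at 260 ± 189 against 767 ± 370 CPM (−1.56, SE 0.39) and Thbs1 (−1.96, SE 0.47). Of 16 histone genes 7 fell (9 adjusted over the list alone; median −0.52, adjusted p = 0.0436). Of 14 cartilage and bone markers 5 fell (2 adjusted over the list alone), among them Col2a1 at 183 ± 235 against 839 ± 716 CPM (−2.19, SE 0.69). The list as a whole did not pass (median −1.69, adjusted p = 0.124). Without the libraries with Hoxb4 over 10 CPM, the calls of Fn1 (−0.83, adjusted p = 0.138), Thbs1 (−1.16, adjusted p = 0.0982) and Col2a1 (−0.67, adjusted p = 0.486) ended. Other lists with higher medians were endocannabinoid genes (8 of 11 rose, 0.53, adjusted p = 0.00703) and thyroid hormone genes (6 of 14 rose and 1 fell, 0.95, adjusted p = 0.0164). So were inhibitory neuron markers (6 of 15 rose, 0.96, adjusted p = 0.0104), dopamine and serotonin genes (11 of 23 rose, 0.77, adjusted p = 0.0241) and cholesterol synthesis genes (12 of 22 rose and 2 fell, 0.30, adjusted p = 0.00469). Adjusted over the list alone, 8, 7, 4, 11 and 12 of these rose and 0, 1, 0, 0 and 2 fell with edgeR. Of 24 cholinergic genes 10 rose and 2 fell (10 and 2 adjusted over the list alone), and the list did not pass (median 0.21, adjusted p = 0.239).

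The genes that the 2 insecticides act on at the protein level moved as follows in DM brains. Ache rose to 39.0 ± 23.9 from 16.03 ± 7.47 CPM (1.28, SE 0.34, adjusted p = 0.00335), a call that ended with both control sets pooled (0.81, adjusted p = 0.0613). Scn1a, at 22.9 ± 10.6 against 11.2 ± 2.85 CPM, rose by 1.03 on the log2 scale (SE 0.21, adjusted p = 0.000281). Scn2a, at 90.8 ± 39.8 against 40.5 ± 11.5 CPM, rose by 1.16 (SE 0.22, adjusted p = 0.000176), and Scn8a by 0.48 (SE 0.15, adjusted p = 0.00885). Scn3a was at 0.19 (adjusted p = 0.481). Bche fell by 0.75 on the log2 scale (SE 0.29, adjusted p = 0.0366), but its call was lost in 9 of the 18 fits that left out 1 library and with pooled controls (−0.66, adjusted p = 0.0616). Without the libraries with Hoxb4 over 10 CPM the calls of Scn8a (0.27, adjusted p = 0.0632) and Bche (−0.38, adjusted p = 0.381) ended.

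The largest rises in DM brains were those of Avp, which encodes the hormone vasopressin, at 4.14 ± 3.33 against 0.0191 ± 0.0463 CPM (7.55, SE 1.16, adjusted p = 1.54e-05). Next were Bpifa1 (6.37), Cryba1 (5.16), the muscle creatine kinase Ckm (4.94), Krt13 (4.93), Mmp13 (4.85), the mast cell tryptase Tpsb2 (4.59), Sec14l3 (4.20), Fam216b (3.91) and Rprml (3.85). Cryba1, Ckm, Krt13, Mmp13 and Tpsb2 were far higher in DM replicate 4 than in the other DM brains. Without that library Cryba1 stood at −0.72 (adjusted p = 0.650), Ckm at −1.08 (adjusted p = 0.537) and Tpsb2 at 2.43 (adjusted p = 0.0210), and DESeq2 did not call Krt13 (0.55, adjusted p = 0.714) or Mmp13 (0.06, adjusted p = 0.960). With both control sets pooled the calls of Avp (2.38, adjusted p = 0.0625), Ckm (0.06, adjusted p = 0.983), Mmp13 (1.65, adjusted p = 0.247) and Tpsb2 (1.47, adjusted p = 0.218) ended.

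The largest falls in DM brains included genes of heart development, Nkx2-5 (−6.31), Tbx5 (−6.06), Hand2 (−4.73) and its neighbour Hand2os1 (−6.45), whose reads cannot be kept apart without knowing the strand. Limma-voom with sample quality weights called none of these 4. Without hyphen-coded control replicate 4, Tbx5 stood at −1.94 (adjusted p = 0.0253) and Hoxd9, a posterior patterning gene, moved from −3.32 to −1.87 (adjusted p = 0.0917). Without the libraries with Hoxb4 over 10 CPM, Tbx5 stood at −0.66 (adjusted p = 0.462), Hand2 at 1.86 (adjusted p = 0.286), Hoxd9 at −0.88 (adjusted p = 0.556) and Hbb-y at −3.10 (adjusted p = 0.0547). The call of Hand2 also ended with both control sets pooled (−3.97, adjusted p = 0.0564). Kap had 0 counts in all 8 DM brains against 1.75 CPM over the controls, at least 193-fold lower with a floor of 3 counts over the group. Against the plain-coded controls, which are unexposed, the log2 fold change of Kap was 0. Gabrp fell from 16.3 ± 8.46 to 0.796 ± 1.26 CPM (−4.34) and Hsd3b6, a steroid-making enzyme, from 16.5 ± 4.14 to 1.59 ± 2.73 CPM (−3.37). Hbb-bh1 fell from 15.1 ± 5.62 to 1.54 ± 2.69 CPM (−3.30, SE 0.95, adjusted p = 0.00607) and Hbb-y from 1120 ± 306 to 118 ± 217 CPM (−3.24, adjusted p = 0.0101).

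To measure what went with the code form and not with a pesticide, the 2 control sets were compared. In brain, plain-coded controls had more Gabra5 (24.8 against 7.30 CPM; log2 fold change 1.76, SE 0.32, adjusted p = 0.000729), Grin1 (44.1 against 17.7 CPM; 1.31, SE 0.26, adjusted p = 0.00114), Camk2b (1.25, adjusted p = 0.00131) and Ache (0.91, adjusted p = 0.0498), and less Mki67 (150.4 against 298 CPM; −0.99, SE 0.25, adjusted p = 0.00571). In all 4985 genes passed, 2635 higher and 2350 lower, and 109 without the libraries with Hoxb4 over 10 CPM. That fit kept only 6 hyphen-coded and 5 plain-coded controls. With edgeR 5269 genes still had an unadjusted p under 0.05, against 7503 with all libraries, so that lost power may account for part of the fall. Of the lists, 15 stood higher and 1 lower with camera. Among them, 15 of 21 synaptic vesicle genes (median 0.70), 11 of 28 glutamate genes (0.47), 10 of 19 GABA genes (0.67) and 47 of 58 oxidative phosphorylation genes (0.28) rose and 13 of 30 cell cycle genes fell (median −0.56). Adjusted over the list alone these counts were 16, 15, 12, 48 and 22, with 1 GABA gene lower (adjusted p = 0.8289 with an estimated correlation for each of these lists).

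The genes that differed between the control sets overlapped those of DM, which was measured against one of these sets. In brain 2408 genes were higher and 1984 lower in both comparisons, 1 went opposite ways, and lists drawn independently would share 596.5 and 507.2. Across genes the fold changes correlated with r = 0.747. In simulations of unchanged groups, libraries of any group were drawn at random after centring on their group means, also for the shared reference. These gave r = 0.403 (covariance 0.232 observed and 0.0324 simulated). The spread of such a reference is not that of the hyphen-coded controls alone. With the hyphen-coded controls split so that the comparisons shared no library, r was 0.690 and 0.564. In placenta 1766 genes were higher and 1204 lower in both, where independent lists would share 339.6 and 257, and 0 went opposite ways. There r was 0.758 (simulated 0.490; covariance 0.166 observed and 0.0255 simulated), or 0.453 and 0.717 with split controls. Genes are not independent replicates, so these correlations describe the libraries and carry no p.

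The same CPF comparison in placenta gave 5 genes, all lower. Zfp869, a zinc finger gene, fell to 13.3 ± 1.28 CPM (SD, n = 16) from 17.8 ± 2.04 CPM in plain-coded controls (n = 9; log2 fold change −0.41, SE 0.06, adjusted p = 0.000334). Asns, asparagine synthetase, fell to 39.2 ± 4.66 from 52.96 ± 6.72 CPM (−0.43, SE 0.08, adjusted p = 0.0251). Pou3f1, a transcription factor, fell to 6.59 ± 2.62 from 15.6 ± 7.51 CPM (−1.24, SE 0.25, adjusted p = 0.0429), and Adamts15, a secreted protease, to 34.2 ± 4.41 from 52.7 ± 16.8 CPM (−0.62, SE 0.13, adjusted p = 0.0471). The pseudogene Ceacam-ps1, named after its values were seen, was at 0.237 ± 0.103 against 3.65 ± 8.95 CPM (−3.93, SE 0.71, adjusted p = 0.0133). Of 19301 genes, 1987 had an unadjusted p under 0.05, DESeq2 called 57, and leaving out 1 library at a time gave between 1 and 22 calls. The Asns call was lost without plain-coded control 15 (adjusted p = 0.0832), 1 (0.0918), 16 (0.0751) or 13 (0.0679). The Pou3f1 and Adamts15 calls were lost in 15 and 18 of 25 such fits and the Zfp869 call in none, and Pou3f1 stood at 0.86 against the hyphen-coded controls. With a replicate block, over the libraries whose number occurs in both groups, 0 genes passed with edgeR (1268 at an unadjusted p under 0.05), and Zfp869 stood at −0.46 and Asns at −0.52 (adjusted p = 0.672 for both). With both control sets pooled 302 genes passed, without Pou3f1 (−0.49, adjusted p = 0.393).

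Genes close to the threshold in CPF placenta were Acvr1 (log2 fold change −0.26, adjusted p = 0.0582), Gon4l (−0.35, adjusted p = 0.0582), Zfp964 (−0.48, adjusted p = 0.0609), Ticrr (−0.48, adjusted p = 0.0609), Ash2l (−0.19, adjusted p = 0.0775) and Doxl2 (−3.19, adjusted p = 0.0809). Ache was at −0.90 (adjusted p = 0.372), Bche at 0.64 (adjusted p = 0.505) and Cyp1a1, a dioxin-inducible enzyme, at 0.39 (adjusted p = 0.665). Scn2a was at 0.31, Scn3a at 0.81 and Scn8a at 0.19 (adjusted p = 0.742, 0.586 and 0.681). Among the lists, 10 stood higher and 4 lower with camera, and 0 held with an estimated correlation. The 20 endoplasmic reticulum stress genes, Asns among them, had a median of −0.16 (adjusted p = 1.27e-10): 1 fell over all genes, and 8 adjusted over the list alone. The 22 spongiotrophoblast genes, which mark the junctional zone of the placenta, had a median of −0.31 (adjusted p = 1.46e-05), with 0 past the threshold over all genes with edgeR and 2 lower adjusted over the list alone. Medians of cytosolic ribosomal protein genes (0.10, adjusted p = 5.05e-12), oxidative phosphorylation genes (0.06, adjusted p = 1.76e-08), microglia and macrophage markers (0.34, adjusted p = 0.000943) and immediate-early genes (0.21, adjusted p = 0.00502; 2 higher adjusted over the list alone) lay above 0. For each of these 6 lists, adjusted p = 0.570 with an estimated correlation, and against the hyphen-coded controls all but the immediate-early genes turned direction.

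**Figure D3:**
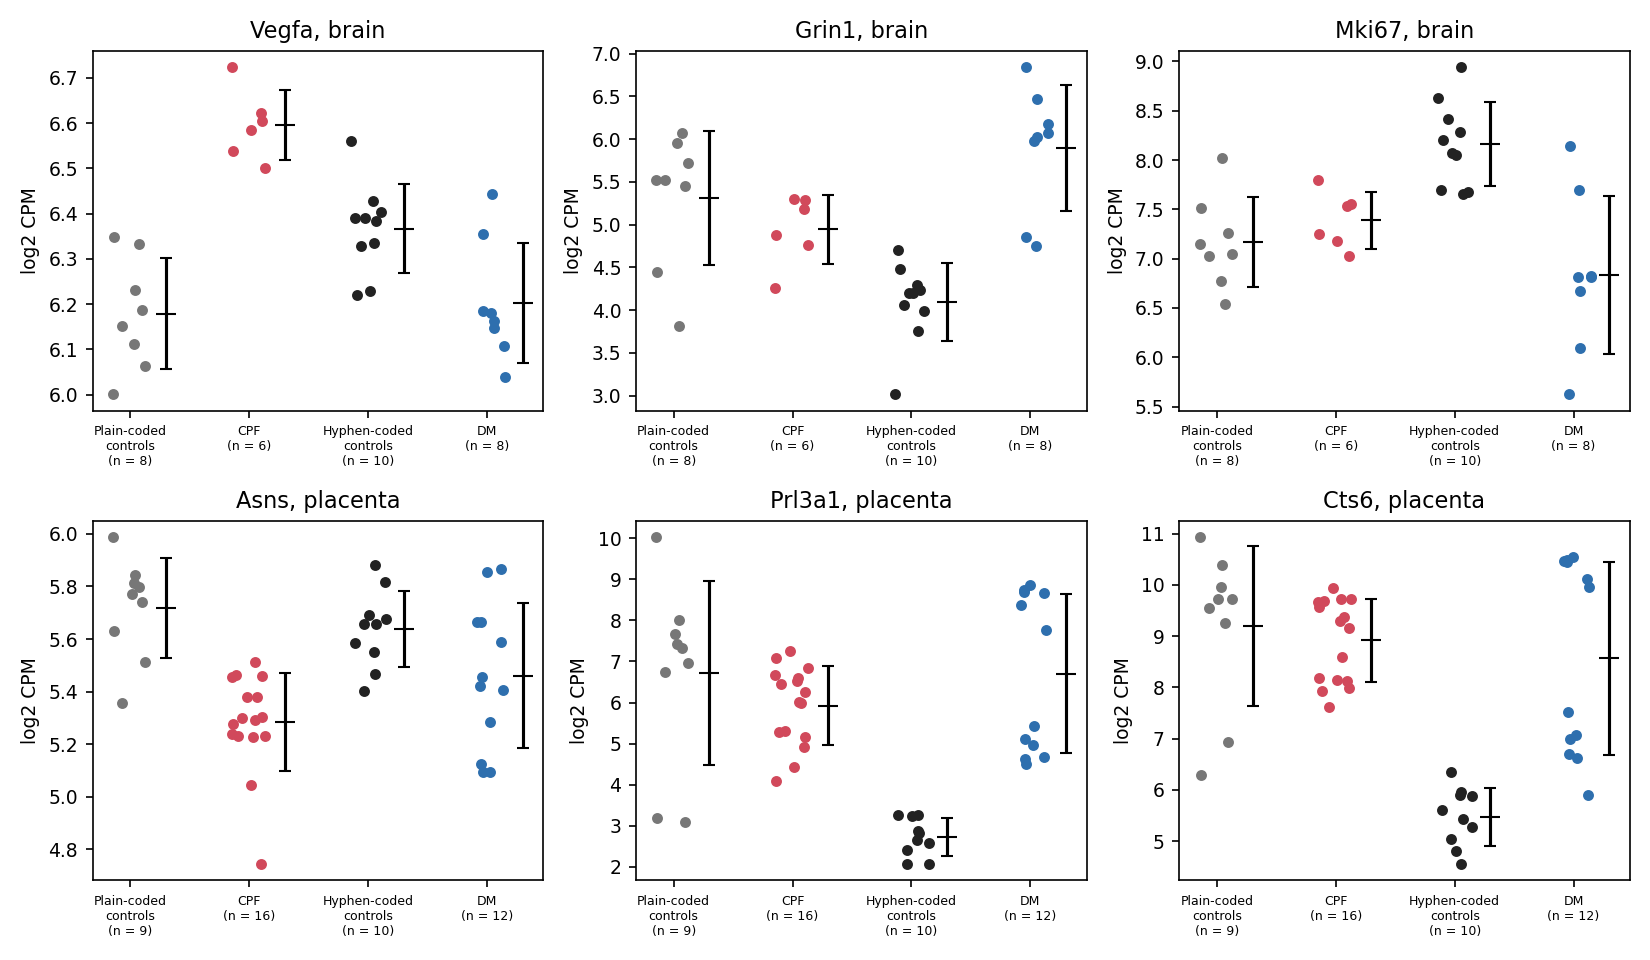
Log2 CPM of 6 genes in each library by group, with points for libraries and bars for the mean ± SD: Vegfa, Grin1 and Mki67 in brain, and Asns, Prl3a1 and Cts6 in placenta. Grin1 ran from 4.75 to 6.84 in DM brains and from 3.02 to 4.70 in hyphen-coded controls, and Prl3a1 from 4.51 to 8.87 in DM placentas, 2.07 to 3.27 in hyphen-coded and 3.10 to 10.03 in plain-coded controls.

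In placenta after DM, most genes of the spongiotrophoblast list rose and most cell cycle genes fell. Prl3a1, a placental member of the prolactin family, was at 204 ± 192 CPM with DM (SD, n = 12) and 6.88 ± 2.10 CPM in hyphen-coded controls (n = 10; log2 fold change 4.89, SE 0.68, adjusted p = 5.40e-06). Cts6, a placental cathepsin, was at 710 ± 633 against 47.5 ± 17.9 CPM (3.90, SE 0.56, adjusted p = 6.39e-06), and Psg16, of the pregnancy-specific glycoproteins, at 7012 ± 4531 against 1031 ± 207 CPM (2.77, SE 0.37, adjusted p = 2.54e-06). Cell cycle genes fell in 28 of 30 cases, with Ccne1 at 7.35 ± 4.08 against 18.5 ± 6.45 CPM (−1.33, SE 0.27, adjusted p = 0.000496). In all 4476 of 19301 genes passed, 2385 higher and 2091 lower, with a median size of 0.36 on the log2 scale. Hyphen-coded control 8 (Xist at 200 and Y-linked RNA at 0.285 CPM) and DM replicate 13 (210 and 52.8 CPM) had sex-linked RNA unlike that of most other placentas, and 4637 genes passed without these 2. Hyphen-coded control 5 (141 and 71.1 CPM) also had both, but lay below the bound set for Xist and was kept. Against the plain-coded controls DM placentas gave 0 calls with edgeR (3255 genes at an unadjusted p under 0.05), where Prl3a1 stood at −0.18, Cts6 at −0.24 and Psg16 at −0.02, and with both control sets pooled there were 162. Pooling ended the calls of Prl3a1 (0.85, adjusted p = 0.4975), Cts6 (0.75, adjusted p = 0.484), Psg16 (0.84, adjusted p = 0.240) and Ccne1 (−0.91, adjusted p = 0.0738). Prolactin, Psg, cathepsin and keratin genes have near-identical copies between which reads can be shared, so single members are uncertain.

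Of the fixed lists in DM placentas, 4 stood higher and 5 lower with camera. Of 22 spongiotrophoblast genes 17 rose and 1 fell (17 and 2 adjusted over the list alone; median 0.71, adjusted p = 7.81e-09). Prl8a8 was at 2760 ± 666 against 1207 ± 175 CPM (1.19, SE 0.15) and Psg23 had a log2 fold change of 1.66 (SE 0.21). Of 11 markers of sinusoidal giant cells 8 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.55, adjusted p = 0.00054), with Ctsq at 1.79 (SE 0.26). Of 26 nutrient transporter genes 14 rose (17 adjusted over the list alone; median 0.32, adjusted p = 7.44e-05), among them the fatty acid transporter Cd36 (0.60, SE 0.12) and the cholesterol exporter Abca1 (0.65, SE 0.14). Of 20 visceral yolk sac markers 4 rose (4 adjusted over the list alone; median 0.55, adjusted p = 0.00343). With an estimated correlation these lists had adjusted p = 0.513, 0.576, 0.553 and 0.8695, and against the plain-coded controls each turned to the lower side. With both control sets pooled the calls of Prl8a8 (0.50, adjusted p = 0.119), Psg23 (0.64, adjusted p = 0.153), Ctsq (0.50, adjusted p = 0.364), Cd36 (0.25, adjusted p = 0.259) and Abca1 (0.40, adjusted p = 0.0882) ended.

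Lower in DM placentas were the cell cycle genes (28 of 30 fell, 29 adjusted over the list alone; median −1.20, adjusted p = 1.97e-23), with Pcna at −0.37 (SE 0.08) and Mcm7 at −0.80 (SE 0.17). Of 43 cytosolic ribosomal protein genes 29 fell (33 adjusted over the list alone; median −0.21, adjusted p = 1.08e-13), such as Rpl4 (−0.29, SE 0.06) and Rps23 (−0.24, SE 0.06). Of 58 oxidative phosphorylation genes 22 fell (28 adjusted over the list alone; median −0.11, adjusted p = 6.69e-07). Of 14 heat shock genes 8 fell (8 adjusted over the list alone; median −0.23, adjusted p = 6.72e-05), including the chaperones Hsp90ab1 (−0.35, SE 0.06) and Hsph1 (−0.44, SE 0.08). Of 13 markers of parietal giant cells 4 fell (6 adjusted over the list alone; median −0.47, adjusted p = 0.00073). Prl7a1 was at 192 ± 113 against 491 ± 197 CPM (−1.35, SE 0.26) and Prl4a1 at −0.95 (SE 0.23). For these lists in turn, adjusted p = 0.513, 0.697, 0.854, 0.180 and 0.697 with an estimated correlation. Against the plain-coded controls the ribosomal protein and oxidative phosphorylation lists turned to the higher side. With both control sets pooled the calls of Pcna (−0.20, adjusted p = 0.145), Mcm7 (−0.56, adjusted p = 0.0649), Rpl4 (−0.14, adjusted p = 0.179), Rps23 (−0.10, adjusted p = 0.307), Prl7a1 (−0.84, adjusted p = 0.0977) and Prl4a1 (−0.70, adjusted p = 0.0764) ended.

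Single genes with the largest rises in DM placentas were Krt15 (6.70, SE 1.35), Kap (64.4 ± 88.8 against 0.955 ± 0.458 CPM; 6.07, SE 1.13) and the sodium channel Scn9a (8.16 ± 8.86 against 0.163 ± 0.0613 CPM; 5.62, SE 0.88, adjusted p = 3.05e-05). Others were Krt4 (5.39), Prl3a1, Doxl2 (4.87), Psapl1, Krt6a (3.93), Krt13 (3.91) and Cts6. The largest falls were those of the chemokine Cxcl5 (0.628 ± 0.571 against 7.93 ± 8.09 CPM; −3.65, SE 0.58, adjusted p = 3.17e-05). Others were Slc13a1 (−3.30), Ccl20 (−2.99), Bhmt (−2.71), Thbs4 (−2.60), Shisal1 (−2.30), Ocm (−2.29), Hbb-bh1 (4.54 ± 4.81 against 21.8 ± 7.23 CPM; −2.26, SE 0.71, adjusted p = 0.0173), Gpr83 (−2.20) and Hpd (−2.07). Pooled control sets ended the calls of Slc13a1 (−2.40, adjusted p = 0.133), Ccl20 (−2.12, adjusted p = 0.1004), Bhmt (−2.13, adjusted p = 0.0955), Thbs4 (−1.96, adjusted p = 0.0742), Shisal1 (−1.75, adjusted p = 0.0569), Ocm (−1.85, adjusted p = 0.0603), Hbb-bh1 (−1.65, adjusted p = 0.156) and Gpr83 (−1.50, adjusted p = 0.0977). Against the plain-coded controls Cxcl5 stood at 0.77, Slc13a1 at 2.88, Ccl20 at 1.75 and Gpr83 at 0.22. Ache rose to 7.22 ± 5.34 from 1.72 ± 0.400 CPM (2.07, SE 0.39, adjusted p = 0.000223) and Cyp1a1 to 5.11 ± 3.55 from 2.39 ± 0.721 CPM (1.09, SE 0.29, adjusted p = 0.00514). Bche (−0.21, adjusted p = 0.685), Scn2a (−0.40, adjusted p = 0.284), Scn3a (0.15, adjusted p = 0.854) and Scn8a (0.14, adjusted p = 0.530) did not pass. Pooling also ended the calls of Scn9a (1.75, adjusted p = 0.166), Krt6a (2.08, adjusted p = 0.0741), Doxl2 (0.65, adjusted p = 0.674), Ache (0.77, adjusted p = 0.240) and Cyp1a1 (0.78, adjusted p = 0.0859).

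Between the control sets of placenta, Psg16 (7102 in plain-coded against 1031 CPM in hyphen-coded controls; 2.78, SE 0.38, adjusted p = 2.73e-06), Prl3a1 (231.9 against 6.88 CPM; 5.08, SE 0.70, adjusted p = 3.56e-06), Cts6 (4.14, SE 0.57) and Ache (2.03, adjusted p = 0.000278) were higher with plain codes, and Mki67 was lower (−1.06, adjusted p = 0.014). In all 5120 genes passed, 2748 higher and 2372 lower. The lists that stood apart were 6 higher and 8 lower. Of 22 spongiotrophoblast genes 17 rose and 1 fell (18 and 2 adjusted over the list alone; median 0.72, adjusted p = 3.99e-08, adjusted p = 0.575 with an estimated correlation). All 38 ribosomal protein genes that passed, of 43, fell (41 adjusted over the list alone; median −0.30, adjusted p = 3.18e-22, adjusted p = 0.575 with an estimated correlation), as did 28 of 30 cell cycle genes (30 adjusted over the list alone; median −0.995, adjusted p = 5.86e-16, adjusted p = 0.650 with an estimated correlation).

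**Figure D4:**
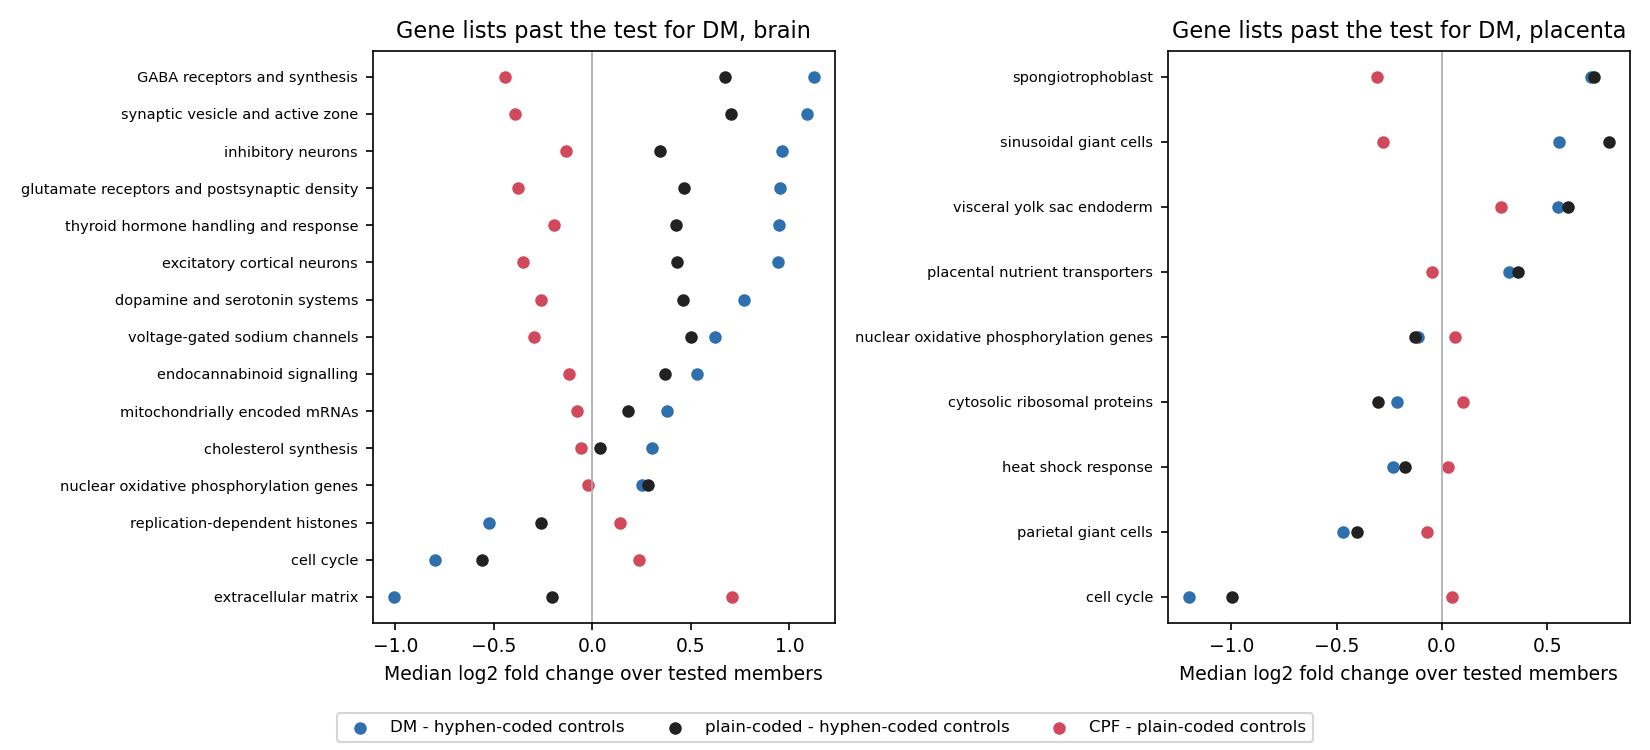
Median log2 fold change of the fixed gene lists past the test for DM with camera, brain on the left and placenta on the right, with points for CPF against plain-coded controls, DM against hyphen-coded controls, and plain-coded against hyphen-coded controls. For the cell cycle list the medians were 0.24, −0.80 and −0.56 in brain and 0.05, −1.20 and −0.995 in placenta.

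Whether the changes with the 2 pesticides differed was tested directly, as the CPF change minus the DM change, each against its own controls. In brain the difference was −3.38 for Gabra5 (SE 0.50, adjusted p = 0.00012), −2.55 for Camk2b, −2.37 for Grin1 (SE 0.41, adjusted p = 0.000186), −1.36 for Ache (adjusted p = 0.0396) and 1.37 for Mki67 (adjusted p = 0.00594). In placenta it was −6.56 for Prl3a1 (SE 0.85, adjusted p = 5.25e-06), −4.50 for Cts6 (adjusted p = 3.12e-05), −3.49 for Psg16 (adjusted p = 6.34e-06) and −2.96 for Ache (adjusted p = 0.00019). The difference passed for 7670 genes in brain, 3739 positive and 3931 negative, and for 2725 in placenta, 1060 positive and 1665 negative. This difference contains that between the control sets. In placenta, log2 CPM of Cts6 averaged 8.92 with CPF, 8.57 with DM, 9.20 in plain-coded and 5.48 in hyphen-coded controls. Prl3a1 averaged 5.93, 6.70, 6.72 and 2.73 in the same order. The counts thus need not reflect the pesticides. Since the 2 control sets themselves differed for many of these genes, the test holds only with the controls of each code form. With the embryonic globin score as a covariate it gave 0 genes in brain (245 at an unadjusted p under 0.05) and 45 in placenta with edgeR. Without the brain libraries with Hoxb4 over 10 CPM, which leaves 3 of CPF, it gave 0 genes in brain with edgeR (5128 at an unadjusted p under 0.05).

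Whether a change differed between the tissues was tested in 1 fit of all libraries, as the change in brain minus the change in placenta. For DM the difference was 2.32 for Camk2b (SE 0.39, adjusted p = 6.45e-06), 2.49 for Grin1 (SE 0.46, adjusted p = 3.37e-05) and 3.94 for Gabra5 (SE 0.95, adjusted p = 0.00116), while Ache (−0.71, adjusted p = 0.334) and Mki67 (0.20, adjusted p = 0.776) did not pass. In all 6182 of 22910 genes passed, 3273 positive and 2909 negative. For CPF 4 genes passed, 3 positive and 1 negative: the lens crystallin Cryaa (9.03, SE 1.56, adjusted p = 0.00385), Bcl3 (1.82, SE 0.37, adjusted p = 0.0432), Gm8343 and Gm21887, all named after their values were seen. Unweighted limma-voom in place of edgeR gave 0 genes (1664 at an unadjusted p under 0.05). With a replicate block of the title code shared by the tissues added to it, 0 genes passed with limma-voom (1690 at an unadjusted p under 0.05), and Cryaa stood at 2.66 (adjusted p = 0.715), Gm8343 at 3.13 (0.0532), Bcl3 at 1.73 (0.529) and Gm21887 at −1.74 (0.361). With a filter at 1 CPM 1 gene passed, Cryaa (adjusted p = 0.00325). Cryaa was at 215.8 CPM in CPF brain replicate 9 and at most 0.530 CPM in the other CPF brains, so that 1 library carried its call.

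Co-expression modules, built in each tissue without regard to group (groups of genes whose levels rise and fall together across libraries), were compared in the same way. In brain 3621 of 5000 genes fell into 9 modules. The mean eigengene, a summary of each module's genes per library, was higher in DM brains by 0.360 for a module of 974 genes led by Faim2, Gabra5, Gng4, Syn2 and Opcml (exact permutation test, 2-sided, p = 4.6e-05, adjusted p = 0.000411). It was higher by 0.238 for 35 genes led by Gpm6a, Lmo3, Grm2, Kcnj9 and Rnd1 (exact permutation test, adjusted p = 0.00151) and by 0.213 for 68 genes led by Foxg1, Sstr2, Tbr1, Zbtb18 and Foxo6 (exact permutation test, adjusted p = 0.0480). It fell by 0.346 for 47 genes led by Igf2bp1, Eme1, Exo1, Dlgap5 and Bub1, several of which act in cell division (exact permutation test, adjusted p = 0.00103). In placenta, with 5 modules of 1449 genes, it fell with DM by 0.247 for 278 genes led by Mcm5, Tpx2, Mcm3, Bub1b and Kif22 (permutation test, p = 0.00016, adjusted p = 0.0004). It was higher by 0.247 for 77 genes led by Cts6, Ctsq, Tns4, Lrp8 and Lepr (permutation p = 2e-05, the smallest that these permutations can give, adjusted p = 0.0001). The 3 genes of the embryonic globin score were members of the 47-gene and 278-gene modules, so eigengenes were built again without them and the other erythroid genes before they were set against the score. As deviations from the group means, the eigengenes of the 974-gene and 47-gene modules of brain correlated with the embryonic globin score across libraries with r = −0.878 and 0.841 (Spearman's rho −0.824 and 0.737, permutation p = 2e-05 and 0.0001; adjusted p of r 9.33e-05 and 0.00021 over 14 relations; r = −0.835 and 0.740 without the 2 libraries farthest from the median). For the 35-gene and 68-gene modules r was −0.228 and −0.184 (rho −0.301 and −0.339, permutation p = 0.0526 and 0.0464; adjusted p of r 0.0262 and 0.322; r = −0.214 and −0.326 without those 2 libraries). For the 278-gene and 77-gene modules of placenta r was 0.929 and −0.890 (rho 0.932 and −0.886, permutation p = 1e-05, the smallest that these permutations can give; adjusted p of r 7e-05; r = 0.9115 and −0.883 without 2 libraries). With CPF 0 modules passed in either tissue, with smallest adjusted p = 0.442 in brain and 0.344 in placenta by exact permutation tests. With both control sets pooled 0 modules passed for DM in placenta, and in brain 1 passed for DM with the 3000 most variable genes and 2 at a network power of 6.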

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

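The splits of the samples and the comparison of DM with the other controls were planned, while every other test weighed for the DM calls, with its scores and simulations, and the left-out libraries were chosen only after the result was seen. How the comparison with the other controls would bear on a batch was also set down only after its result was seen.

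The CPF and DM changes, each against its own controls, differed for 7670 genes in brain and 2725 in placenta. These counts include the difference between the control sets. The tissues differed for 6182 genes after DM and 4 after CPF. Of 100 splits of the libraries, 1 gave as many calls, the real one, for CPF against DM in brain (highest other 3231) and in placenta (highest other 345). The same held for DM in brain (9034, highest other 4501) and placenta (4476, highest other 3052). It also held between the control sets of brain (4985, highest other 0) and placenta (5120, highest other 1227). For the tissue difference after DM, 1 of 50 splits gave as many (6182, highest other 1358), again the real one. If the libraries of a group are independent, chance could thus be excluded for the DM counts within a tissue and for the control sets. The labels do not give litters, and litters or collections shared within a group would undo this. For CPF against DM, the splits shuffled all libraries of a tissue over its 4 groups. They show only that these groups were not all alike, and cannot single out a difference between CPF and DM. The tissue splits removed the DM change in each tissue, and 49 splits other than the real one still gave calls, so that they do not test for equal changes. For CPF in brain the real split gave 1 gene, again as 1 of 100 splits as large, and the highest other gave 0, but a single gene whose call ends with only the 2 groups in the fit (0 calls) cannot carry an exclusion of chance. Chance could not be excluded for the calls of CPF in placenta (5, with 6 of 100 splits as large and a highest other of 521), nor for the CPF tissue difference (4, with 4 of 50 splits as large and a highest other of 7). A split of the placenta libraries that gives 521 calls where the real one gives 5 points to a structure of these samples that does not follow the CPF label.

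The numbers of gene lists past the threshold could not be told from chance either. For CPF in brain 13 lists passed (77 of 100 splits as large, highest other 30), for DM in brain 15 (54 of 100, highest other 29), for CPF in placenta 14 (26 of 100, highest other 23) and for DM in placenta 9 (70 of 100, highest other 23). The preset correlation of camera makes list p-values too small in samples with such structure, and splits of any kind called lists.

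The many calls for DM may reflect fetuses at a later developmental stage than the hyphen-coded controls. Slopes of each gene on the embryonic globin score, estimated only in CPF and plain-coded control libraries, predicted the DM fold changes across genes with r = 0.7938 in brain and 0.6401 in placenta, where scores permuted within groups gave a median size of r of 0.357 and 0.241 and at most 0.777 and 0.649 (0 and 2 of 1000 as large). With the score as a covariate DM calls went from 9034 to 0 in brain (550 genes at an unadjusted p under 0.05, edgeR) and from 4476 to 87 in placenta, mainly because the changes shrank: the median size of the called genes' fold changes went from 0.60 to 0.15 in brain (median SE 0.15 and 0.20) and from 0.36 to 0.13 in placenta (median SE 0.098 and 0.095). The scores of DM and hyphen-coded controls did not overlap, however. The highest DM and lowest control scores were 6.84 and 6.87 in brain and 7.54 and 7.76 in placenta. The adjusted comparison thus rests on a straight line extended between the groups, and the loss of calls cannot by itself tell stage from DM. The tables argue against a library batch that follows the code form as the cause of the DM calls, since DM differed from the controls of its own form. Against the plain-coded controls DM gave 0 calls in brain and 0 in placenta (edgeR, 2884 and 3255 genes at an unadjusted p under 0.05). These 0 calls do not show that the groups are alike, and a batch as part of the difference between the control sets was not tested. Nor was a batch that separates DM from the controls of its own form. The last number of the sample titles, whose meaning is not given, ran from 515 to 524 in hyphen-coded control placentas and from 525 to 541 in DM placentas. The tables also argue against deltamethrin alone, since the unexposed plain-coded controls shared the DM fold changes with a covariance of 0.2317 in brain and 0.166 in placenta, which 0 of 200 simulations of unchanged groups reached (highest 0.171 and 0.0812). They argue too against hindbrain and spinal cord or cartilage and bone tissue as the whole cause in brain. With their scores, which differed by −0.91 and −1.31 between DM and its controls, as covariates 9930 and 9459 calls were left and the median size of the called genes' fold changes was 0.58 and 0.50. Open are meninges in some brain libraries (8353 calls and a median size of 0.47 with that score as a covariate), such tissue as part of the cause, since the calls of Fn1, Thbs1, Col2a1, Tbx5, Hand2 and Hoxd9 ended without the libraries with Hoxb4 over 10 CPM, and whether deltamethrin itself moved the stage or acts beside it.

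Single libraries lay far from the others of their group for 23 of 199 groups of values. Chance flags about 1 in 20 groups of normally distributed values. Most values here were of genes picked by their results, which 1 far library can bring about, so that rate does not apply directly. Placenta CPF (n = 16) and DM (n = 12) were too large for this test, so that no library of theirs could be flagged. In brain, in log2 CPM, these were CPF replicate 9 for Cryba1 (6.513) and Crybb3 (6.02), and DM replicate 4 for Cryba1 (6.15), Ckm (6.93), Krt13 (4.575), Mmp13 (3.868), Tpsb2 (3.426) and Nkx2-5 (−2.588). Among plain-coded control brains they were replicate 17 for Ciart (1.038) and replicate 11 for Hdac9 (4.081). Among hyphen-coded control brains they were replicate 4 for Bpifa1 (−2.404), Tbx5 (5.776) and Camk2b (4.642), replicate 5 for Avp (−2.379), replicate 6 for Gabrp (−0.866) and replicate 9 for Cryba1 (−2.793). In placenta, plain-coded control replicate 1 stood apart for Adamts15 (6.56), Cyp1a1 (−0.492) and Acvr1 (5.792), hyphen-coded control replicate 9 for Kap (−3.482) and Krt4 (−4.42), replicate 7 for Psapl1 (−4.42) and replicate 3 for Scn2a (−2.492).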

How the results depend on the processing

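Leaving out libraries, the embryonic globin, skeletal muscle, hindbrain, cartilage, meninges and yolk sac scores, limma-voom without weights for the tissue difference and the block shared by the tissues were chosen only after the result was seen, and the other alternatives were planned. The number of DM calls in brain (9034) stayed within 1.5 times with DESeq2, sample quality weights, both filters, RLE size factors, a Y-linked score, 2 surrogate variables, the muscle, hindbrain, cartilage and meninges scores, only the 2 groups in the fit, and libraries with Hoxb4 over 10 CPM left out (7025). The placenta count (4476) did so with these, where run, and with the yolk sac score. With pooled controls the DM counts were 5356 in brain, 162 in placenta and 3157 for the tissue difference. With the controls of the other code form they were 0 and 0, for which the report gives the counts at an unadjusted p. With the globin score, counts were 0 for DM in brain, 87 for DM in placenta, 10 for CPF in placenta, 1 and 1847 between the control sets of brain and placenta, and 0 and 45 for CPF against DM. CPF counts in brain (1) were 4 with DESeq2, 5556 with sample quality weights, 2 with RLE size factors, 3 with 2 surrogate variables, 4 with the muscle score, 2 with the hindbrain score, 3 with the cartilage score, 3 with the meninges score, 0 without libraries over 10 CPM of Hoxb4, 0 with pooled controls, 0 with only the 2 groups and 2601 with the other controls. CPF counts in placenta (5) were 57 with DESeq2, 75 with sample quality weights, 3 without a filter, 3 with a filter at 1 CPM, 64 with 2 surrogate variables, 55 with the yolk sac score, 302 with pooled controls and 4893 with the other controls. Sample quality weights also gave 9126 genes between the control sets of brain, 11856 and 4811 for CPF against DM in brain and placenta, and 2773 for the CPF tissue difference. Without libraries over 10 CPM of Hoxb4, 109 genes passed between the control sets of brain (edgeR, 5269 at an unadjusted p under 0.05) and 0 for CPF against DM in brain. Surrogate variables gave 8447 between the control sets of brain and 5459 for CPF against DM in placenta, and a filter at 1 CPM gave 1 for the CPF tissue difference. Tests that bear on the weighted CPF calls in brain, the globin score with DM and the block of the tissue difference are given in their passages. For the remaining alternatives, except where one is built from other samples, the cause was not tested.

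Leaving out 1 library at a time gave 1 to 2 calls for CPF in brain, 7922 to 9675 for DM in brain, 1 to 22 for CPF in placenta and 3786 to 5002 for DM in placenta. For CPF in brain 2 genes passed without plain-coded control 11 or 15 or CPF replicate 13. For CPF in placenta 22 passed without plain-coded control 17, 12 without control 14, 9 without control 18, 8 without control 11, 2 without control 15, 16 or 13, and 1 without control 1. Among CPF replicates of placenta, 15 passed without replicate 10, 9 without 11, 8 without 7, and 3 without 2, 14, 8, 5, 6, 13, 16, 9 or 4. Without hyphen-coded control brain 5, low in both Xist and Y-linked RNA, brain DM calls were 8891, 4774 genes passed between the control sets and 7575 for CPF against DM. Without placenta hyphen-coded control 8 and DM replicate 13, whose sex-linked RNA was also unusual, placenta counts were 4637 for DM, 9 for CPF, 4800 between the control sets and 2998 for CPF against DM.

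Title numbers do not pair the samples. The correlations of same-numbered libraries ran from −0.41 to 0.09 over 4 pairs for CPF in brain, −0.31 to 0.66 over 8 for DM in brain, −0.48 to 0.16 over 7 for CPF in placenta and −0.38 to 0.54 over 10 for DM in placenta. In these comparisons 0, 1, 0 and 2 libraries correlated best with their own number. With the number as a replicate block, over the libraries whose number occurs in both groups, calls were 0 for CPF in brain, 0 for CPF in placenta, 7625 for DM in brain and 4929 for DM in placenta. For the tissue difference, limma-voom without weights or a block gave 0 genes for CPF and 5547 for DM, and with a replicate block of the title code shared by the tissues 0 and 5682, so that the move from 4 to 0 came with the test and not with the block.

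With an estimated correlation 0 lists passed for CPF in brain, 0 for DM in brain, 0 for CPF in placenta and 0 for DM in placenta. With the globin score 8 passed for CPF in brain and 16 for DM in placenta. Of the DM modules, 1 passed in brain with 3000 genes and 2 at power 6, and 0 passed in placenta with pooled controls.

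Of the named genes, those that turned direction were few outside the globin score and the other controls. Cryba1 in brain DM stood at −0.27 with sample quality weights. Leaving out 1 library at a time, Cryba1 in brain DM ran from −0.72 (without DM replicate 4) to 5.35, and Ckm in brain DM from −1.08 (without that library) to 5.49. With the globin score Gabrp stood at 0.47, Hbb-bh1, itself part of that score so that this was fixed by construction, at 0.17 and Ache at −0.18 in brain DM, and Doxl2 at −0.28 in placenta DM. Without libraries over 10 CPM of Hoxb4, Hand2 in brain DM stood at 1.86. With the other controls Ckm stood at −1.09 and Uqcrq at −0.047 in brain DM, and Pou3f1 at 0.86 in placenta CPF. In placenta DM they gave −0.18 for Prl3a1, −0.39 for Doxl2, −0.24 for Cts6, 0.77 for Cxcl5, 2.88 for Slc13a1, 1.75 for Ccl20, 0.22 for Gpr83, 0.015 for Pcna, 0.029 for Rpl4, 0.0585 for Rps23, −0.0055 for Prl8a8, −0.0071 for Psg23, −0.018 for Psg16, −0.23 for Ctsq, 0.10 for Prl7a1 and −0.062 for Cd36. Beyond these, 73 named genes lost their call with the globin score, 65 with the other controls, 39 with pooled controls, 10 without libraries over 10 CPM of Hoxb4, and at most 8 under any other setting that changes 1 choice for all comparisons. Of the 73 genes, 52 kept under 50% of their fold change with the globin score, but 12 kept at least 2 of 3 parts of it. These 12 included Ccl20, Thbs4, Hpd and Prl4a1 in placenta. The others were Bpifa1, Cryba1, Krt13, Mmp13, Kap, Nkx2-5, Tbx5 and Bche in brain, where the fold change of Kap has no bound at 0 counts with DM. The SE of these 12 grew, as from 0.29 to 0.50 for Bche (−0.75 to −0.84) and from 0.59 to 0.72 for Thbs4 (−2.60 to −2.71). For these 12 the lost call thus does not show that the score takes up the change. Depth limits little here, since total counts ran only from 40779368 to 43795738.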

Other observations

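The tests on the sample codes and on the sample weights were chosen only after the result was seen, while the gene lists were planned.

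Other gene groups and cell types showed mixed or small changes after DM. In brain 10 of 18 angiogenic factors and receptors fell and 1 rose (median log2 fold change −0.29, adjusted p = 0.0613 with camera), 12 of 29 imprinted genes fell and 6 rose (−0.56, adjusted p = 0.124), and 8 of 17 genes of the oligodendrocyte lineage, the cells that make myelin, rose and 2 fell (0.40, adjusted p = 0.09). Of 15 markers of meninges and fibroblasts 6 fell and 2 rose (−1.02, adjusted p = 0.09), and of 13 skeletal muscle markers 1 rose (median −0.05 and mean 0.29, adjusted p = 0.741). Of 16 erythroid genes 7 fell and 3 rose in brain (adjusted p = 0.239), and 3 fell and 4 rose in placenta (adjusted p = 0.368). In placenta 8 of 26 hypoxia and glycolysis genes rose and 1 fell (0.18, adjusted p = 0.157), and 3 of 17 genes of xenobiotic metabolism rose (0.13, adjusted p = 0.384). No such list passed, so that these counts describe single members. Adjusted over the list alone they were, in the order given, 10 and 1, 12 and 7, 8 and 2, 6 and 3, 0, 7 and 3, 4 and 5, 8 and 1, and 3.

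Between the control sets of placenta, groups beyond those of the report also stood apart. Of 29 imprinted genes 13 rose with plain codes (14 adjusted over the list alone; median 0.21, adjusted p = 0.00095, adjusted p = 0.654 with an estimated correlation). Of 25 genes of the NRF2 oxidative stress response 11 fell and 1 rose (13 and 1 adjusted over the list alone; median −0.23, adjusted p = 0.000705, adjusted p = 0.654 with an estimated correlation). The 15 markers of uterine natural killer cells, maternal cells of the decidua, had a median of −0.96 with 2 lower (2 adjusted over the list alone; adjusted p = 0.0162, adjusted p = 0.768 with an estimated correlation).

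Sample quality weights raised the CPF calls in brain from 1 to 5556, and the weights themselves, not the limma-voom test, are a candidate explanation, since limma-voom without them gave 2. With weights estimated anew in each of 100 splits of the 14 CPF and plain-coded control libraries, 10 splits gave as many calls and the highest other gave 9738, so that chance could not be excluded. Among these 14 libraries the highest weight was 7.09 times the lowest, over all brain libraries weights ran from 0.225 to 3.11, and 1 library held 30.6% of the weight of the CPF group. Splits that call more genes than the real one point to a structure among these libraries that does not follow the label. A response to CPF that only the weighted test detects was not tested further.

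Brain and placenta libraries shared 32 title codes, taken as the letters, code form and first number. The last number of the titles differed between the tissues, as 501 in brain and 519 in placenta for hyphen-coded control 10. The same code does not mark the same conceptus, since the sex shown by Y-linked RNA differed for 17 of the 32. The same code may mark the same litter or collection. Over the 32 codes, embryonic globin scores of brain and placenta, as deviations from their group means, correlated with r = 0.8901 (p = 5e-04, permuting codes within groups) and Spearman's rho of 0.763 (p = 2e-04 by the same permutation test), and with r = 0.7999 without the 2 codes farthest from the median. Within groups r was 0.891 for CPF (n = 6), 0.937 for plain-coded controls (n = 8), 0.898 for DM (n = 8) and −0.159 for hyphen-coded controls (n = 10), in which the score varied least. No code occurs again within a group of a tissue. If codes mark litters, each library of a group would thus come from another litter, the unit of exposure, and only the fit of both tissues would repeat litters. Differences between litters in age at collection could then add to the spread that the p-values measure.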
